A study of Mus musculus with 2 samples.

How the data were processed

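MicroRNA sequencing libraries (RNA below 30 nt) from the left cerebral cortex of 14 day old female B6CASTF1/J mice were analysed, with 2 biological replicates in 1 group, as the labels give them. The labels record separate biosamples but the same donor record for both, and they do not say whether that record stands for an animal or for the strain; the label of replicate 1 mentions several females. Statements on spread therefore concern these 2 libraries, and part of the spread may be technical.

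The deposited files hold whole read counts per microRNA gene, made by the authors with the mouse build mm10 and the GENCODE M21 annotation, per the file headers and the list of files that came with them. Trimming settings, aligner and counter are not given in the sources used here. Each file has 3 unnamed columns of counts and 4 rows that name no gene. The meaning of the columns was taken from the values: 1 column counts reads without regard to strand, 1 on the RNA strand and 1 on the opposite strand. The RNA strand was used throughout, since the column without strand sets aside reads at the 64 loci that overlap a locus on the opposite strand.

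The rows that name no gene were left out of library sizes. In replicate 1 they held 1403582 unmapped reads (18.1% of 7745369), 3142330 reads that mapped to several places (40.6%), 459125 reads on no microRNA gene (5.93%) and 0 ambiguous reads on the RNA strand. In replicate 2 they held 2193590 unmapped reads (22.8% of 9627908), 3645348 reads that mapped to several places (37.9%), 581029 reads on no microRNA gene (6.03%) and 0 ambiguous reads. The gene-assigned totals were 2740332 and 3207941 reads. The exact binomial 95% intervals of these gene-assigned shares were 35.35% to 35.41% and 33.29% to 33.35%. At least 1 read was counted at 674 and 694 loci. Reads that mapped to several places stand in a row of their own and enter no deposited gene count, and the files do not give the loci they came from.

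Gene symbols, coordinates and host genes were looked up in the GENCODE M21 annotation on mm10, in which all 2202 identifiers matched. Host genes are those on the same strand. Where several overlapped a locus, protein-coding genes were ranked first, and within each kind genes with a clone name were ranked last. This ranking was chosen after the first results were seen. Hairpin sequences were taken from the same release, and a locus was counted as sharing sequence when a stretch of 20 nt was identical in another microRNA locus, which held for 1084 loci.

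Levels are gene-assigned reads scaled to a library total of 1000000 (CPM). A locus was detected when it had at least 10 reads in each library. Correlations used log2(CPM + 1). Between the libraries, the reads of each detected locus were tested with a two-sided exact binomial test against library sizes scaled with edgeR's TMM, and p-values were adjusted by Benjamini and Hochberg over the 389 detected loci, with a threshold of 0.05. The spread beyond counting was edgeR's common dispersion with an intercept as the only term. Neuron-enriched and other-tissue loci were compared by a permutation test with 100000 resamples, and shared and single-copy loci by an exact sign-flip permutation over 12 families. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean level. Members of a random list were drawn independently, whereas ratios of sequence relatives were correlated. Percentiles of lists made of relatives may therefore be too extreme. The lists overlap in part, and the percentiles were not adjusted for the number of lists. Where 4 or fewer loci of a list were detected, the median rests on those loci.

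The 18 lists were neuron-enriched, Dlk1-Dio3, let-7, miR-29, oligodendrocyte, microglial and leukocyte, endothelial and mural, erythroid, choroid plexus, epithelial, miR-183 cluster, muscle, liver with gut and pancreas, early embryo, X-linked testis, miR-17~92 with paralogs, shared mature sequence and single-copy relatives. The lists, the families, the tests, the detection minimum, the alternatives and the rule for naming loci were fixed before the data were examined. Named loci were the 20 with the highest mean CPM, up to 4 of each list with the highest mean CPM, the 10 with the largest absolute log2 ratio among those with a mean of at least 100 reads and an adjusted p under 0.05, and members of the 12 families. Loci outside this rule are identified as such where they appear.

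Alternatives were the column without strand, a minimum of 5 or 50 reads or none, a pseudocount of 5, DESeq2 size factors, library totals without further scaling, and each replicate left out in turn. With 1 group there was no comparison between groups, no paired design and no other split of the samples to draw, and groups of 2 are too small to look for outlying libraries.

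The procedures were tested on simulated counts for the same 389 loci. A coefficient of variation of 0, 0.2 and 0.4 was recovered as 0.0019, 0.204 and 0.394. Of 50 loci simulated at each size, the binomial test called 78.0% at 1.5-fold, 90.0% at 2-fold, 94.0% at 4-fold and 100% at 8-fold, and it called 6 of 189 unchanged loci (3.17%). The counts for the binomial test were drawn with counting noise alone. Its rates therefore do not carry over to the real libraries, whose biological coefficient of variation was 0.317. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.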

Results

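Small RNA below 30 nt was sequenced from the left cerebral cortex of 14 day old female mice of the strain B6CASTF1/J, an F1 hybrid of C57BL/6J with a CAST strain. The labels give 1 group of 2 biological replicates and no treatment, genotype or second tissue. The comparisons are therefore between the replicates and among microRNA loci within them. The label of the first replicate speaks of several females and that of the second of a single female, and whether the first library pools animals is not stated. The files hold whole read counts for 2202 annotated microRNA loci (GENCODE M21, mouse build mm10). Replicate 1 held 7745369 reads, of which 2740332 (35.4%) were counted on the RNA strand of a microRNA locus. Replicate 2 held 9627908 reads, of which 3207941 (33.3%) were counted in this way. Levels are given as normalised read counts (CPM), in which the gene-assigned reads of a library are scaled to 1000000, as mean ± SD over n = 2 libraries. A count of 0 allows up to 3 reads, which is 1.09 CPM in replicate 1 and 0.935 CPM in replicate 2. Intervals and floors cover counting error only, since no molecular identifiers are stated.

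The first question was which microRNA loci supplied the gene-assigned reads of the cortex at this age. Reads that mapped to several places are left out, 40.6% of all reads in replicate 1 and 37.9% in replicate 2. The ranking therefore covers gene-assigned reads only and can miss microRNAs encoded at several loci. Mir139 was the most abundant locus, at 83247 ± 21345 CPM (SD, n = 2). It was followed by Mirlet7i at 78903 ± 20031 CPM and Mirlet7g at 70800 ± 24921 CPM, both members of the let-7 family, which is known for rising as tissues differentiate. Mir127, from the imprinted Dlk1-Dio3 region, reached 65239 ± 5196 CPM, and Mirlet7b reached 64261 ± 7866 CPM. The spread of Mir139, Mirlet7i and Mirlet7g between the libraries was wider than the gaps between these 5 loci, so their order was not resolved.

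Mir139 (chromosome 7, 101475376 to 101475443) lies in an intron of Pde2a, a phosphodiesterase gene. Mirlet7i (chromosome 10, 122985640 to 122985724) overlaps an exon of the pseudogene transcript D630033A02Rik. Mirlet7g (chromosome 9, 106178840 to 106178927) lies in an intron of Wdr82, and Mirlet7b (chromosome 15, 85707319 to 85707403) in an exon of the non-coding Lncppara. Mir127 (chromosome 12, 109592846 to 109592915) has no annotated host on its own strand. Places 6 to 10 went to Mir770 (36617 ± 6635 CPM), Mirlet7d (30311 ± 4364 CPM), Mir99a (28827 ± 622 CPM), Mir744 (23376 ± 3317 CPM) and Mir433 (22306 ± 1427 CPM). Mir770 lies in an exon of the maternally expressed non-coding RNA Meg3, and Mir744 in an intron of the kinase gene Map2k4. Mirlet7e, Mir382, Mir652, Mir23b, Mir149, Mir99b, Mir126a, Mir487b, Mir541 and Mir30d completed the 20 most abundant loci, from 21742 ± 2476 CPM for Mirlet7e to 12505 ± 1157 CPM for Mir30d. Mir126a, known from endothelium, lies in Egfl7, and Mir652 lies in an intron of Tmem164 on the X chromosome.

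The 10 most abundant loci held 51.7% of gene-assigned reads in replicate 1 and 49.0% in replicate 2 (50.4 ± 1.90%, n = 2). The 50 most abundant held 84.2 ± 0.758%. Loci within introns of protein-coding genes on the same strand gave 36.2 ± 1.39% of reads, loci in non-coding host genes 37.0 ± 1.95%, loci in exons of protein-coding genes 5.24 ± 0.175%, and loci without a host 21.5 ± 0.379%. Altogether 389 loci had at least 10 reads in each library and are called detected below. No read was counted at 1450 loci in either library. Of these, 949 (65.4%) share an identical stretch of 20 nt with another locus, against 1084 of all 2202 loci. Reads within such a stretch map to several places and are not counted, so 0 reads there do not show that a microRNA is absent.

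Lists of microRNAs known from particular cell types and tissues were compared next, to describe which are represented in the cortex. Neuron-enriched loci were far above loci known from muscle, liver, gut, pancreas, epithelia, early embryo and testis. Of 21 annotated neuron-enriched loci 17 were detected, and together they held 4.31 ± 0.690% of reads (n = 2). Mir128-1 led the list at 10267 ± 6918 CPM, followed by Mir132, an activity-regulated microRNA, at 9108 ± 961 CPM, Mir137 at 7452 ± 1255 CPM and Mir138-1 at 5222 ± 2216 CPM. The 58 loci of the other 5 tissue lists held 0.0503% of reads, and 11 of them were detected. The mean log2(CPM + 1) was 7.67 for neuron-enriched and 1.30 for other-tissue loci, a difference of 6.37 (two-sided permutation test across loci, p = 2e-05, the smallest that the resamples can give). Loci are not independent replicates. Most neuron-enriched loci, Mir128-1 and Mir138-1 among them, and several other-tissue loci share their mature sequence with another locus. Counts at such loci are mostly low and leave out reads that mapped to several places, as described below. The share and the order of the neuron-enriched list are therefore uncertain.

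Among the other-tissue lists, Mir375 of endocrine cells reached 151 ± 41.7 CPM and the liver microRNA Mir122 52.0 ± 12.7 CPM. Mir429 reached 65.4 ± 15.1 CPM, Mir203 59.2 ± 26.9 CPM and Mir200c 18.8 ± 3.38 CPM among epithelial loci. The muscle list was led by Mir206 at 30.0 ± 1.66 CPM, with Mir499 at 9.12 and 16.8 CPM in replicates 1 and 2, and the heart loci Mir208a and Mir208b at 8 and 3 reads in replicate 1 and 15 and 16 reads in replicate 2. None of the 14 early embryo loci and none of the 18 X-linked loci known from testis was detected. Mir302d, of pluripotent cells, had 2 and 8 reads, and Mir470, of the X-linked list, had 7 in each library. The miR-183 cluster of sensory cells held 61 reads in replicate 1 and 100 in replicate 2, and Mir96 of that cluster had 0 in both, which allows up to 1.09 CPM in replicate 1 and 0.935 CPM in replicate 2.

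Lists of non-neuronal cell types held shares of gene-assigned reads between those of the neuron-enriched list and the pooled other-tissue lists. Endothelial and mural loci held 1.74 ± 0.538% of reads, led by Mir126a at 13066 ± 5198 CPM and by Mir143, known from smooth muscle, at 4186 ± 224 CPM. Oligodendrocyte loci held 0.288 ± 0.198%, with Mir219a-2 at 2096 ± 1758 CPM and Mir338 at 923 CPM in replicate 1 and 613 CPM in replicate 2, so the spread of Mir219a-2 was nearly as large as its mean. Microglial and leukocyte loci held 0.173 ± 0.0230%, with Mir150 at 793 ± 389 CPM, Mir146 at 2388 and 2102 reads in replicates 1 and 2, Mir155 at 102 ± 27.3 CPM and Mir142 at 59.7 ± 12.1 CPM. Choroid plexus loci held 0.105 ± 0.0110%, led by Mir204 at 669 ± 317 CPM, and erythroid loci 0.0782 ± 0.0276%, led by Mir451a at 709 ± 281 CPM. The miR-29 family, described as rising with neuronal maturation, held 0.156 ± 0.00395% of reads, led by Mir29a at 1198 and 1387 CPM in replicates 1 and 2. The miR-17~92 cluster with its paralogs, known from proliferating cells, held 0.743 ± 0.00501%, led by Mir93 at 2905 ± 202 CPM and Mir17 at 2170 ± 582 CPM.

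**Figure D1:**
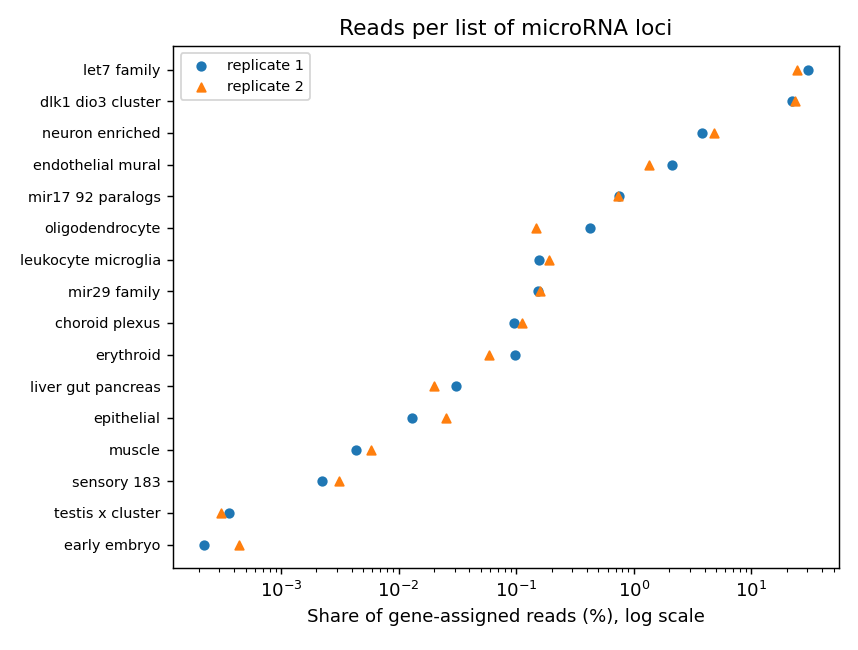
Share of gene-assigned reads (%, log axis) of 16 lists of microRNA loci in replicate 1 (circles) and replicate 2 (triangles). The let-7 family holds 30.5% and 24.6% of reads, and the early embryo list 0.00022% and 0.00044%.

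The imprinted Dlk1-Dio3 region, whose microRNAs are transcribed from the maternal chromosome, supplied 22.9 ± 0.817% of gene-assigned reads (22.4% in replicate 1 and 23.5% in replicate 2). Of 57 listed loci 49 were detected. Mir127 held the highest level at 65239 ± 5196 CPM, followed by Mir770 at 36617 ± 6635 CPM, Mir433 at 22306 ± 1427 CPM and Mir382 at 18432 ± 2956 CPM. Mir487b reached 12650 ± 4754 CPM and Mir541 12528 ± 1559 CPM. Of the listed loci 56 span 184.27 kb of chromosome 12, from 109563692 to 109747960, and 54 of these lie on the plus strand. The remaining locus, Mir496b, is annotated on chromosome 19, outside the region, and had 0 reads in either library; it was named after its position was seen. Chromosome 12 as a whole held 23.9 ± 0.927% of reads and the X chromosome 4.16 ± 0.392%.

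**Figure D2:**
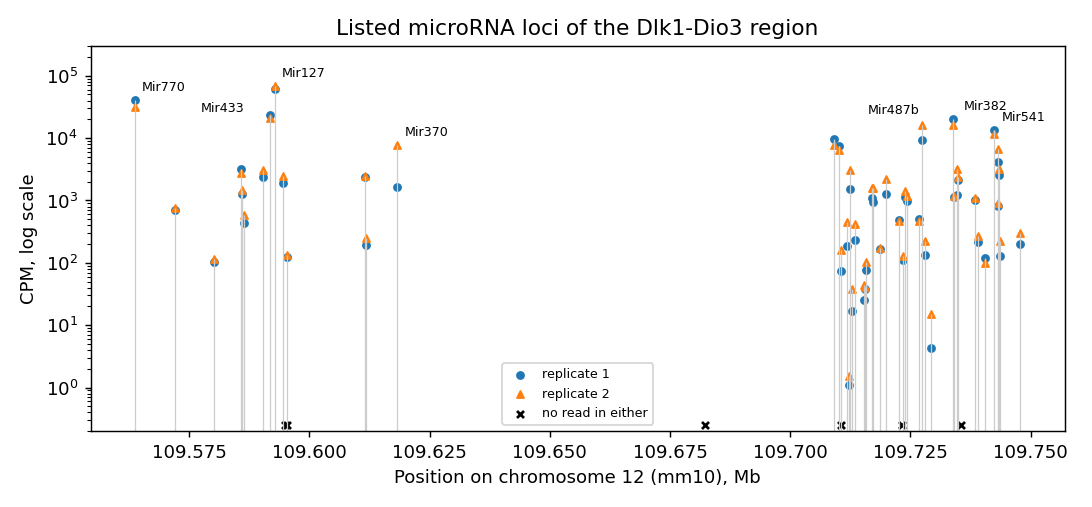
Levels in CPM (log axis) of the listed loci of the Dlk1-Dio3 region against their position on chromosome 12 in Mb (mm10), in replicate 1 (circles) and replicate 2 (triangles); crosses at the bottom mark loci without a read in either library. Mir127 reaches 61564 CPM in replicate 1 and 68913 CPM in replicate 2, and Mir370 1616 and 7718 CPM.

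Loci whose mature microRNA is encoded at several places in the genome were then compared with single-copy relatives of the same family. The shared loci had a lower mean log2(CPM + 1) per locus in 11 of 12 families. In the let-7 family, the 6 shared loci, led by Mirlet7f-2 at 2052 ± 348 CPM and Mirlet7c-2 at 1995 ± 25.9 CPM, differed from the 6 single-copy loci by −5.82 on the log2 scale. Mir26a-1 and Mir26a-2 had 10.1 ± 9.58 and 15.3 ± 5.67 CPM, against 4673 ± 2273 CPM for Mir26b, and Mir103-1 and Mir103-2 had 10.2 ± 7.31 and 38.8 ± 32.8 CPM, against 2894 ± 2717 CPM for Mir107. The mean difference over families was −3.47 ± 2.85 log2 units (SD, 12 families), an 11.1-fold lower geometric mean (two-sided exact sign-flip permutation test, p = 0.00244, where the smallest possible p is 0.00049).

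The exception was the family of miR-25 and miR-92, in which Mir92-1 (855 ± 477 CPM) and Mir92-2 (21.3 ± 3.33 CPM) averaged 1.31 log2 units above Mir25 (54.5 ± 21.3 CPM). In the miR-19 family Mir19a, Mir19b-1 and Mir19b-2 had at most 2 reads in a library, so its difference of −0.12 lies at the floor. Each of the 46 annotated loci with a shared mature sequence held a stretch of at least 20 nt identical to another microRNA locus, against 2 of the 23 single-copy relatives, Mir29c and Mir107. Reads that mapped to more than 1 place were set aside in these counts and made up 40.6% of all reads in replicate 1 and 37.9% in replicate 2. Counts at loci with a shared sequence are therefore uncertain as levels of the mature microRNA. Mir128-1, Mir138-1, Mir146, the oligodendrocyte locus Mir219a-2, Mir23b and Mir487b are included.

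The neuronal microRNAs miR-124 and miR-9 belong to this class and were named after their values were seen. Mir124a-1 (chromosome 14, 64590657 to 64590741), Mir124a-2 (chromosome 3, 17795662 to 17795770) and Mir124a-3 (chromosome 2, 180894040 to 180894107) lie in exons of non-coding transcripts and share the stretch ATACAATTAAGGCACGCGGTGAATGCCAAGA of 31 nt. They had 6, 5 and 0 reads in replicate 1 and 10, 12 and 7 reads in replicate 2. Mir9-1 (chromosome 3, 88215598 to 88215686), Mir9-2 (chromosome 13, 83738814 to 83738885) and Mir9-3 (chromosome 7, 79505264 to 79505353) share TCTTTGGTTATCTAGCTGTATGAGTG, of 26 nt, and reached means of 22.4 ± 5.83, 1.95 ± 1.21 and 109 ± 12.6 CPM. Mir128-1 (chromosome 1, 128202361 to 128202430, intron of R3hdm1) and Mir128-2 (chromosome 9, 112118636 to 112118711, intron of Arpp21) share TCTCACAGTGAACCGGTCTCTTT, of 23 nt, and had 14732 and 6095 reads in replicate 1 and 48629 and 15794 reads in replicate 2.

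**Figure D3:**
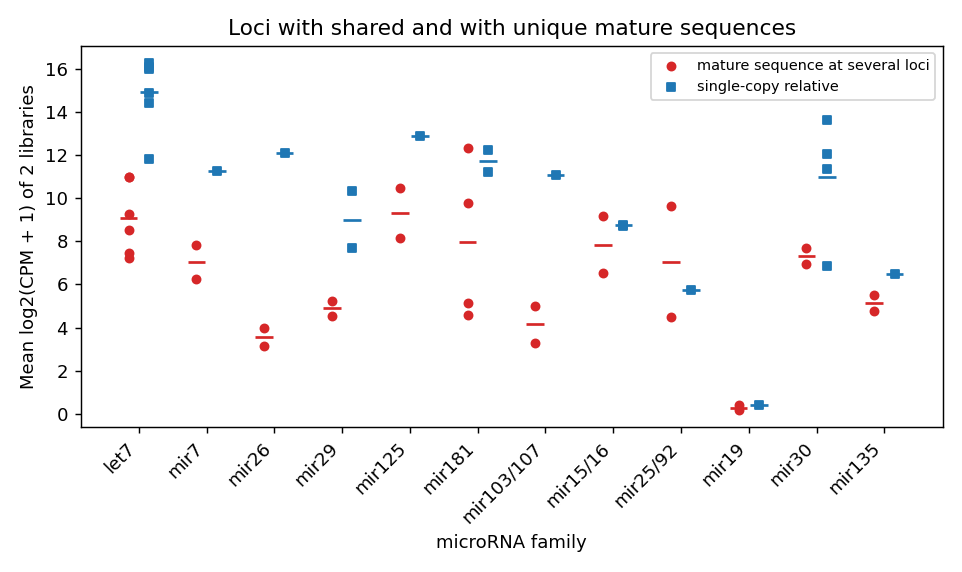
Mean log2(CPM + 1) of the 2 libraries for loci with a mature sequence found at several loci (red circles) and for single-copy relatives (blue squares) in 12 microRNA families; short lines are means. The shared loci average lower in 11 of the 12 families, with differences of −8.54 in miR-26 and −6.92 in miR-103 and miR-107.

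The last question was how far the replicates resembled each other. The ranking of loci was closely similar, but the levels of single loci differed between the libraries. Relative to replicate 1, replicate 2 was higher in Mir301 (log2 ratio 2.24), the epithelial Mir200b (2.12), Mir370 of the Dlk1-Dio3 region (2.08), Mir148a (2.06) and Mir1298, in an intron of the serotonin receptor gene Htr2c (2.06). It was lower in Mir31 (−3.16), Gm23935 (−3.08), Mir107 (−2.48), Mir103-2 (−2.17) and the oligodendrocyte locus Mir219a-2 (−2.14). Ratios are of reads scaled by trimmed mean of M values (TMM), and the tests compare these libraries only, not conditions. Their p-values cover counting error only, not the spread between animals or preparations, so a count of loci past the test describes this pair of libraries and is no finding about the loci.

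Over the 389 detected loci, Pearson's r of log2(CPM + 1) was 0.982 (bootstrap 95% interval over loci 0.977 to 0.986) and Spearman's rho was 0.978, across loci, which are not independent replicates. A chi-square test of homogeneity gave 190358 with 388 degrees of freedom (491 per degree), so the libraries are not 1 library deposited again. The biological coefficient of variation from edgeR's common dispersion was 0.317 (bootstrap 95% interval over loci 0.280 to 0.348). The interval resamples loci of the same 2 libraries, so it leaves out the uncertainty of having only 2 replicates. The log2 ratio had an SD of 0.70. A total of 262 loci (67.4%) lay within 1.5-fold. By a two-sided exact binomial test with Benjamini-Hochberg adjustment over the detected loci, 227 differed, 112 higher and 115 lower in replicate 2. Of these 44 differed by at least 2-fold, 25 higher and 19 lower, and this count was 25 when at least 50 reads were required. Scaling by library total alone moves the median log2 ratio from −0.0098 to 0.16, and the split to 159 higher and 77 lower.

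**Figure D4:**
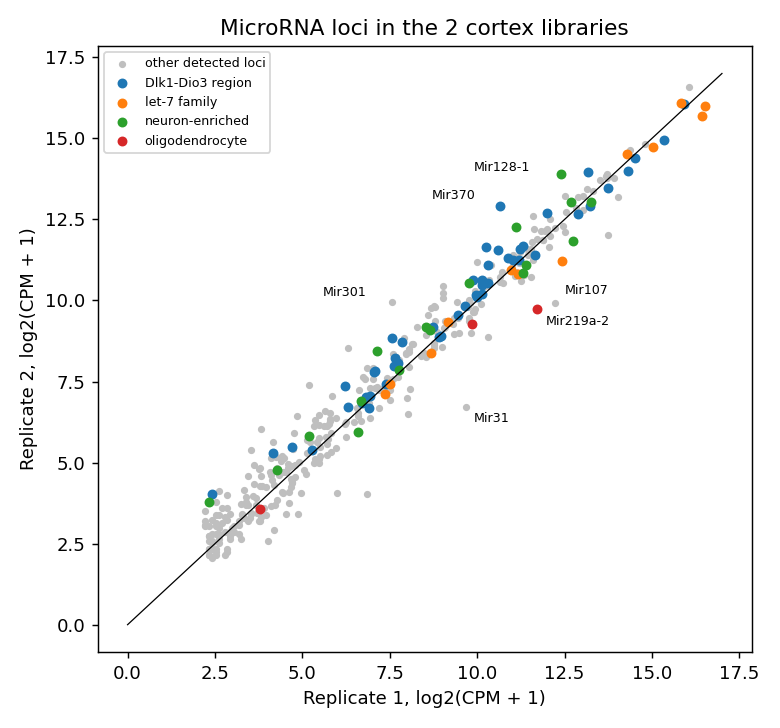
Levels of the 389 detected loci in replicate 2 against replicate 1, both as log2(CPM + 1), each point 1 locus, colored by list, with the line of equal level. Mir31, Mir107 and Mir219a-2 lie below the line, and Mir301, Mir370 and Mir128-1 above it.

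The let-7 family was lower in replicate 2. It held 30.5% of reads in replicate 1 and 24.6% in replicate 2. By the exact binomial test, 9 of its 12 loci were lower and 2 higher (11 differed when adjusted over the list alone). Past the test, 7 were lower and 3 higher when scaled by library total, and 8 lower and 1 higher in the column without strand. Mirlet7g had a log2 ratio of −0.91 and Mirlet7i of −0.70, while Mirlet7b (0.078) and Mirlet7e (0.060) were higher. The family's median was −0.45, at percentile 1.25 among 10000 random lists of the same size and level. Neuron-enriched loci went the other way, with 9 higher and 5 lower past the test (14 differed when adjusted over the list alone), a median of 0.27 and percentile 98.19, which was 0.22 at percentile 96.4, inside the central 95%, in the column without strand. Mir128-1 was higher by 1.32 log2 units, and Mir138-1 was lower (−1.07). Of the Dlk1-Dio3 loci 22 were higher and 12 lower past the test (36 differed when adjusted over the list alone), with a median of 0.16 at percentile 99.34, and 33 were higher and 7 lower past it when scaled by library total. In the column without strand the Dlk1-Dio3 median was 0.048 at percentile 91.75, inside the central 95% of random lists.

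The liver, gut and pancreas list had a median of −0.74 at percentile 0.76, with each of its 5 detected loci lower and 4 past the test, among them Mir375 (−0.74) and Mir217 (−1.73), or 2 past it with at least 50 reads required, although it held only 0.0306% and 0.0200% of reads. The miR-29 family had a median of −0.57 at percentile 1.8, with 3 of 4 loci lower and 2 of them past the test, Mir29c at −0.98 among these, and with 1 higher and 2 lower past it when scaled by library total. Its share of reads was not lower in replicate 2 (0.159%) than in replicate 1 (0.153%). Mir29a, its most abundant locus, had a ratio of 0.038 and did not pass the test. Loci with a shared mature sequence had a median of −0.20 at percentile 2.04, with 9 higher and 18 lower past the test, and 12 higher and 13 lower past it when scaled by library total; in the column without strand the percentile was 2.94, inside the central 95%. Against the median, the share of reads of these shared loci was higher in replicate 2 (4.28%) than in replicate 1 (3.46%). Their single-copy relatives had a median of −0.21 at percentile 9.94. Adjusted over the list alone, 4 loci differed in the liver, gut and pancreas list, 2 in the miR-29 family, 27 with a shared sequence and 20 single-copy relatives.

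Lists of other cell types lay within the central 95% of random lists. Oligodendrocyte loci held 0.428% of reads in replicate 1 and 0.148% in replicate 2, with both abundant members, Mir219a-2 and Mir338 (−0.76), lower and a median of −0.76 at percentile 3.76. Endothelial and mural loci held 2.12% and 1.36%, with Mir126a lower (−1.01) and Mir145a higher (0.36), at percentile 24.81. The erythroid list had a median of −0.36 at percentile 21.19, with Mir451a lower (908 CPM in replicate 1 and 510 CPM in replicate 2). Choroid plexus loci had a median of −0.42 at percentile 4.52, with Mir204 higher (0.83) and Mir34c (−1.73) and Mir449a (−1.17) lower. Epithelial loci had a median of 0.55 at percentile 92.64, with Mir200b and Mir203 (0.79) higher. Microglial and leukocyte loci had a median of −0.17 at percentile 29.24, with Mir150 higher (0.87), and the miR-17~92 paralogs a median of −0.12 at percentile 26.92; both medians were above 0 when scaled by library total (0.0034 and 0.054). In the column without strand, which sets aside the reads of Mir219a-2, Mir338 and Mir451a, 0 oligodendrocyte and 0 erythroid loci passed the test. There the microglial and leukocyte median, without Mir142, was −0.59 at percentile 2.4, outside the central 95%. Adjusted over the list alone, 2 oligodendrocyte, 3 endothelial and mural, 1 erythroid, 3 choroid plexus, 2 epithelial, 3 microglial and leukocyte and 7 miR-17~92 loci differed. The muscle and miR-183 lists had 2 detected loci each, none of which differed, although Mir499 passed the test when scaled by library total (log2 ratio 0.88), and no percentile was computed for them.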

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

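The tests of pairs of related or neighbouring loci, and the reading of the family test and of the multimapping ratio as tests of explanations, were chosen only after the counts had been seen; the family test itself and the test of GC content were set beforehand.

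Reads that mapped to several places or to no microRNA gene lay outside the counts used for the comparisons, above the 3 reads that a count of 0 allows for a single row. Reads that mapped to several places numbered 3142330 in replicate 1 and 3645348 in replicate 2. Reads on no microRNA gene numbered 459125 and 581029. The opposite-strand column held 190504 and 216955 reads, of which 99.93% and 99.95% lay at loci that overlap a partner on that strand, where they are also the RNA-strand reads of the partner and so part of the counts used: Mir126b held 45873 and 30121 of them, against 45876 and 30124 RNA-strand reads of Mir126a. Among loci without such a partner, 9 had over 3 opposite-strand reads in a library.

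Loci with a shared mature microRNA had few reads, Mir26a-1, Mir103-1 and Mirlet7a-2 among them. A candidate explanation is that reads of a sequence present at several loci were set aside, and low transcription of these loci could give the same counts. How far either explains the low counts cannot be told. The mean within-family difference of −3.47 log2 units (exact permutation p = 0.00244, 12 families) is the pattern itself and favors neither. At least 1.14 reads were set aside for each gene-assigned read, without the files saying from which loci. The miR-25 and miR-92 family goes the other way, at 1.31. A read that lies wholly in a stretch identical at several loci maps to several places and is counted at none of them. Low counts at these loci are therefore no evidence that their mature microRNAs are scarce in the cortex. No other biological explanation was tested.

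The log2 ratios of the libraries had an SD of 0.70 over 389 loci, of which 227 passed a test that covers counting error only. A linear trend on the GC content of the whole hairpin is argued against as the whole cause. Removing it lowered the SD of the log2 ratio by 0.5% (bootstrap 0.005% to 2.04%). The trend itself was present (Spearman's rho 0.158 across loci, permutation p = 0.0024). The GC content of the sequenced RNA, which is below 30 nt, was not tested. Sequence-dependent capture during library preparation remains a candidate: in 53 pairs of loci that share 14 nt but lie on other chromosomes or over 1 Mb apart, standardized ratios correlated at 0.540 (one-sided permutation p = 0.0017), falling to 0.347 (p = 0.0109) without the pair Mir103-2 and Mir107, to 0.279 (p = 0.042) in 35 pairs that share no 20 nt, and to 0.301 (p = 0.0993) in the 15 of these without let-7, and rising to 0.806 (p = 0.0015) in 28 pairs when let-7 alone was left out. Shared transcription of neighbours within 10 kb cannot be told apart from chance, with a correlation of 0.069 in 318 pairs (one-sided permutation p = 0.0891) and −0.022 in 52 pairs without chromosome 12 (p = 0.5463). Exchange of reads between near-identical loci, common regulation of paralogs and differences between the animals stay open and were not tested.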

How the results depend on the processing

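All alternatives were set beforehand. Of the recomputed values of the main results, 41 held and 3 moved. A value held when it kept its direction and its side of the threshold, or stayed within its spread or, for counts, within 1.5 times. Some of the 41 could not move. The share of the 10 most abundant loci does not use the read minimum. Another scaling adds a constant to every ratio, which leaves the percentiles of the lists as they were. The share of the 10 most abundant loci was 54.1% in the column without strand, in which 26 detected loci, Mirlet7e and Mir126a among them, fell below 10 reads because reads on overlapping loci are set aside there. With at least 50 reads required, r was 0.975 and 25 of 283 loci differed by 2-fold; the cause was not tested. Without 1 or the other replicate, the top share was 49.3% to 51.7%, the neuron-enriched difference 6.20 to 6.55 and the family difference −3.48 to −3.45. With a pseudocount of 5 the neuron-enriched difference was 5.00 and the family difference −3.35. In the column without strand they were 5.91 and −3.13. The count of loci that differed was at most 240 and stayed within 1.5 times of 227. Scaled by library total, the ratios of Mir99a (0.044), Mir99b (0.071) and Mir181d (0.0083) reversed, since this scaling adds a constant to every ratio. Mir127 (0.16), Mir149 (0.17) and Mir93 (0.14) also changed sign and passed the test there, which they had not with TMM. Mirlet7c-2 (−0.027) and Mir106b (−0.034) were among the loci that no longer passed it. The count of lists outside the central 95% of random lists went from 6 to 4 in the column without strand, and not with the same lists: the neuron-enriched and Dlk1-Dio3 medians moved inside it (0.22 at percentile 96.4 and 0.048 at 91.75), as did that of the shared loci (−0.20 at 2.94). Members of these lists that overlap a partner have 0 reads in that column and drop out of the medians. Mir9-1, Mirlet7f-1 and, outside the naming rule, Mir409 are among them. How far this accounts for the moves was not tested. The microglial and leukocyte median moved out of the central 95% in that column (−0.59 at 2.4), since Mir142 has no reads in it and Mir146 becomes the median of the remaining 3 loci. No paired analysis was possible because there is only 1 group. Depth limits ratios at loci near 10 reads.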

Other observations

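The column without strand was an alternative set beforehand; which of its loci to describe, and Mir191, were chosen only after the values had been seen, and no further test was run.

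Several abundant cortical microRNA loci overlap an annotated microRNA on the opposite strand, and nearly all their reads came from 1 strand. Mirlet7e had 54784 reads in replicate 1 and 75363 in replicate 2 on its own strand. Mir126a had 45876 and 30124, and its partner Mir126b had 0 in both libraries. The oligodendrocyte loci Mir219a-2 (9151 and 2736 reads) and Mir338 (2529 and 1967 reads), the erythroid Mir451a (2489 and 1637 reads) and Mir30e (6597 and 9203 reads) were also of this kind. In the column without strand, Mirlet7e, Mir338, Mir451a and Mir30e had 0 reads in both libraries, Mir126a had 3 in each, and Mir219a-2 had 0 and 1. Mir191, named after its values were seen, went from 27622 and 34033 reads to 0. Oligodendrocyte loci held 0.288% of reads on the RNA strand and 2e-05% in the column without strand, endothelial and mural loci 1.74% and 0.467%, and erythroid loci 0.0782% and 0.00521%.

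Mir107 in Pank1, Mir103-2 in Pank2 and Mir103-1 in Pank3, which lie in introns of paralogous pantothenate kinase genes, had log2 ratios of −2.48, −2.17 and −1.79. The shared sequence of these 3 loci leaves open whether their reads are independent.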
